A study of Homo sapiens with 22 samples.

How the data were processed

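The samples were total RNA preparations of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen and is easily transfected. Per the labels, the cells had been transfected either with a small interfering RNA (siRNA) against Satellite III (Sat III) transcripts or with a scrambled siRNA. Sat III transcripts are long non-coding RNAs copied from pericentromeric repeats, and heat shock factor 1 (HSF1) is known to switch them on in heat-stressed human cells, where they gather in nuclear stress bodies. Cells of each arm were left at 37 °C, heat-shocked for 1 h at 42 °C in a water bath, or heat-shocked and then returned to 37 °C for 6 h. Per the labels' protocols, RNA was purified on silica columns, and 300 ng of it was amplified and labelled with biotin for hybridisation to Illumina bead arrays. The 22 arrays fell into 6 groups. The scrambled arm had 4 untreated, 4 heat-shocked and 4 recovering samples, and the Sat III siRNA arm had 3 untreated, 3 heat-shocked and 4 recovering samples. The labels give replicate numbers and nothing about separate cultures, so the p-values measure the spread between these samples, which may be technical.

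The deposited scanner table holds an intensity for each of 48803 probes on each array, on a linear scale, with no background subtracted and no normalisation between arrays, as judged from values whose medians and maxima differ between arrays. It also holds, per the file headers, a detection p-value for each probe, which compares the probe with negative control beads. The software that made these values is not given in the sources used here. Median intensities ran from 64.6 down to 48.9, and 13176 to 14863 probes per array, or 27.0% to 30.5%, had a detection p-value under 0.01. The authors also deposited a normalised table of intensity values on a linear scale, with a median of 56.2 on each array and no background subtracted. Its centring and scale beyond that are not given in the sources used here.

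The labels of the deposited tables did not match for part of the arrays. Of the 22 columns of the authors' normalised table, 15 had the same order of probes as the scanner column of the same label, counted as the same at a rank correlation above 0.9999. Another 6 columns, those labelled replicate 4, each had the order of the scanner array that precedes the one of the same label, and 1 column, labelled Sat III siRNA, recovery, replicate 3, matched no scanner column, with a highest rank correlation of 0.844. In turn, the scanner column of Sat III siRNA, recovery, replicate 4 had no counterpart. The values of these 7 scanner arrays went with the groups of the scanner table. HSPA6 was at 4.56 to 4.87 on those it labels untreated, 12.58 to 12.75 on heat-shocked and 9.61 to 10.60 on recovering ones, against 4.59 to 4.89, 13.64 to 13.74 and 9.61 to 10.33 in replicates 1 and 2, where both tables agree. A score over 91 siRNA genes picked in replicates 1 and 2 was 0.014 to 0.028 on those it labels scrambled and 0.73 to 0.88 on those it labels Sat III siRNA, against at most 0.027 and at least 0.74 in replicates 1 and 2. The authors' label gave another treatment for each of the 6 matched arrays and another arm for 2 of them. This check was chosen after the data had been seen. The scanner table, whose columns carry names that the sample descriptions repeat, was used for all main results, and the authors' table served as an alternative, once as labelled and once with the 15 matching arrays.

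Intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc estimated the mean and spread of the negative controls from the detection p-values, corrected the background by normexp, added an offset of 16, and then applied quantile normalisation and log2. Probes were kept when the detection p-value was under 0.01 on at least 3 arrays, which left 15324 probes. Gene names came from the platform's annotation table. Of all probes, 28098 had 1 gene symbol there and the other 20705 did not, 13 of them because they had several, and 28059 symbols could be brought up to date through their gene number. Among the tested probes, 13097 had 1 symbol and 2227 did not. Each gene was represented by its brightest tested probe on average over all arrays, which gave 10147 genes. For 2423 genes more than 1 probe was tested, and in 1453 of them all probes had the same sign of change after heat shock in the scrambled arm. No probe was named for Sat III (0 of 48803), so the knockdown of the target itself was not analysed here.

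A gene with a detection p-value at or above 0.01 on every array of a group was treated as not above background in that group. For such genes a fold is given as "at least": the mean of the brighter group was set against, for each array, the higher of the lowest detected signal and the probe's own signal. That lowest detected signal lay between 5.21 and 5.62 on the log2 scale. HSPA1A and HSPA1B have nearly identical sequences, so their probes may respond to either transcript and their separate values are uncertain.

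A linear model with 1 mean per group was fitted to all 22 arrays (lmFit, eBayes), with 16 residual degrees of freedom and a prior worth 5.41. The 11 comparisons were heat shock and recovery against untreated cells and recovery against heat shock in both arms, Sat III siRNA against scrambled siRNA in the 3 treatments, and the interactions of the siRNA with heat shock and with recovery. P-values from limma were two-sided and adjusted by Benjamini-Hochberg within each comparison, and a gene passed at an adjusted p under 0.05. Errors are standard errors (SE) of the log2 fold change unless stated otherwise. The number of arrays limits the precision: the median SE was 0.10 to 0.12, and 0.16 and 0.15 for the interactions with heat shock and with recovery.

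Before the data were examined, the sample groups, the tests, most of the alternatives, 30 gene lists and the rule for named genes were fixed. The rule named, among genes past the threshold whose arrays did not overlap between the groups, the 12 largest rises and the 12 largest falls, or the 6 largest of each for recovery against heat shock and for the interactions. Where fewer than 6 genes passed, the 6 with the smallest p were named. It also named up to 4 members of each list with the smallest p, and always HSPA1A, HSPA1B, HSPA6, DNAJB1, HSPH1, HSF1, SAFB, SRSF1, ACTB and GAPDH. Locus-only symbols could be skipped. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists within each comparison. Camera asks whether the genes of a list shift relative to the other genes. Camera with an estimated correlation and fry, a rotation test, were run as alternatives. Fry asks whether the genes of a list move on balance in 1 direction, without setting them against others. The tested lists covered cytosolic chaperones and HSF1 targets, mitochondrial chaperones and proteases, endoplasmic reticulum stress, the ATF4 and amino acid response, immediate early genes, oxidative stress, p53 targets and growth arrest, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, SR proteins and CLK kinases, nuclear stress body and hnRNP proteins, heterochromatin and centromere proteins, ribosome biogenesis and MYC targets, ribosomal proteins and translation factors, the proteasome, ubiquitin and autophagy, the interferon response, NF-kB and cytokines, cholesterol biosynthesis, hypoxia and glycolysis, targets of TGF-beta, BMP and YAP, mitochondrial respiration, the RNA interference machinery, and housekeeping genes. Metallothioneins, snoRNA host genes, and markers of fibroblasts and endothelium, of keratinocytes and cervical carcinoma, and of blood cells had too few tested members. The signs of median, mean and camera test differed in 42 of the 275 list results and in 0 of those past the threshold.

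Deviations from the group means differed on the whole between the arrays of replicates 1 and 2 and those of replicates 3 and 4, without a clean separation. The first principal component of these deviations held 19.6% of their variance, with scrambled untreated replicate 2 (2.93) and Sat III siRNA heat shock replicate 2 (0.85) on the side of replicates 3 and 4, and scrambled untreated replicate 3 (-2.32) on the other. The median correlation of the deviations was 0.0865 between replicates 1 and 2 or 3 and 4 and -0.117 across that division. Counts and list medians are therefore also given with this division as a block and within each side of it, an alternative chosen after the data had been seen. In the Sat III siRNA arm, replicates 3 and 4 hold 1 untreated and 1 heat-shocked array, which are then assumed to vary like the other groups. No 2 arrays of a group were duplicates: the SD of the log2 difference between them was 0.187 to 0.304.

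The fit was tested on simulated data built on the 10147 genes, with 50 changed genes at each of 4 sizes. For heat shock against untreated cells in the scrambled arm it recovered 20% of changes of 0.25 log2, 76% of 0.5, 96% of 1 and 100% of 2, with 8 false calls among 154. For the interaction with recovery the shares were 0%, 42%, 90% and 100%, with 12 false calls among 128, and for the interaction with heat shock 2%, 30%, 80% and 100%, with 6 among 112. Camera called the 1 simulated list shifted by 0.3 log2 and 0 of the unshifted ones. The simulated genes varied independently of each other and without a batch, unlike the real arrays. These figures therefore do not show how limma and camera behave with correlated genes. Alternatives covered the scaling between arrays, the background correction, the detection filter, the probe standing for a gene, the replicate number as a block, array weights, the prior on the variance, the arrays in the fit, a 1.5-fold minimum, and leaving out arrays. Median scaling set the arrays level at the median of all probes, mostly undetected, and so rests on signals near background. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.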

Results

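RNA levels were measured in HEK293T cells transfected with Sat III or scrambled siRNA. The cells were untreated, heat-shocked (42 °C, 1 h), or heat-shocked and then returned to 37 °C for 6 h. The series title links Sat III RNAs to the heat shock response and to proliferation, so the comparisons ask which genes respond to heat and recovery in each arm and how Sat III siRNA alters them. The scrambled arm had 4 arrays per treatment, and the Sat III siRNA arm had 3 untreated, 3 heat-shocked and 4 recovering arrays. Before normalisation, the median intensity ranged from 64.6 (scrambled siRNA, untreated, replicate 1) to 48.9 (Sat III siRNA, recovery, replicate 3), with 13176 to 14863 probes detected per array. After filtering, 10147 genes were tested. No probe was named for Sat III transcripts (0 probes), so their level was not analysed. Changes are log2 fold changes ± SE, with the group sizes above. The reference genes ACTB and GAPDH did not pass the threshold in any of the 11 comparisons with limma.

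The first comparison asked how scrambled-siRNA cells had changed at the end of the heat shock. HSPA6, a strictly stress-inducible HSP70 gene, rose by 8.39 ± 0.24, or at least 221-fold (limma, adjusted p = 9.1e-17, 4 against 4 arrays). DNAJB1, an HSP40 co-chaperone, rose by 4.42 ± 0.09, or 21.4-fold, and BAG3, a co-chaperone of HSP70, rose by 2.41 ± 0.10, or 5.33-fold. HSPH1, of the HSP110 family, rose by 1.46 ± 0.10, or 2.76-fold. HSPA1A rose by 3.53 ± 0.33, at least 5.81-fold, and its near-identical copy HSPA1B by 1.96 ± 0.07, and these separate values are uncertain. ZFAND2A, a proteasome-associated zinc finger gene induced by stress, rose by 2.35 ± 0.12. Of the 40 tested cytosolic chaperones and HSF1 targets, 25 rose, 0 fell and 15 did not pass (27 rose and 1 fell when adjusted over the list alone). Their median was 0.54 and camera's adjusted p was 1.1e-35, against 0.000397 with an estimated correlation. HSF1 itself, the main transcription factor of the heat shock response, did not pass, at -0.16 ± 0.23. SAFB and SRSF1, proteins known from nuclear stress bodies, did not pass at 0.04 ± 0.10 and 0.08 ± 0.07.

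**Figure D1:**
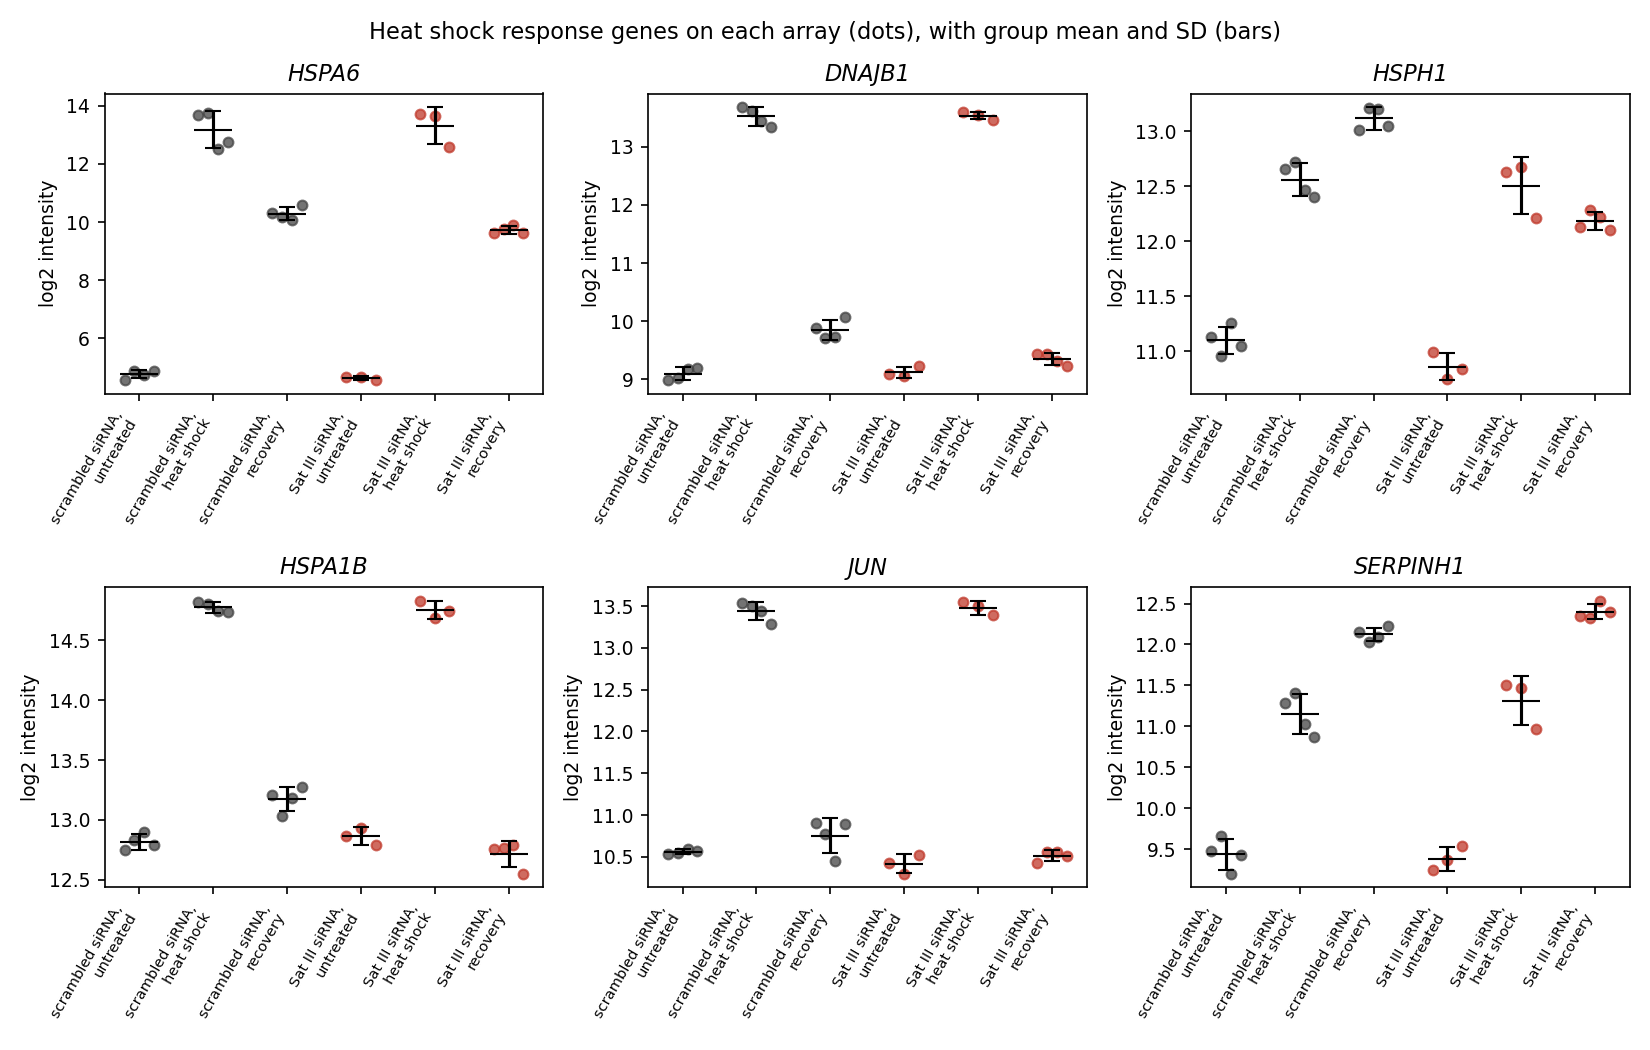
Log2 normalised intensity (vertical axis) of HSPA6, DNAJB1, HSPH1, HSPA1B, JUN and SERPINH1 in each of the 6 groups (horizontal axis), with dots for single arrays and the mean ± SD of each group. HSPA6, DNAJB1, HSPA1B and JUN were highest in the heat-shocked groups, whereas SERPINH1 rose in recovery by 2.69 in the scrambled arm and by 3.02 in the Sat III siRNA arm.

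Immediate early genes, which respond to stimuli without new protein synthesis, formed the next group. DUSP1, a MAP kinase phosphatase gene, rose by 3.45 ± 0.13, or 10.9-fold. JUN, which codes for an AP-1 subunit, rose by 2.88 ± 0.09, or 7.35-fold, ATF3, a stress-induced transcription factor gene, by 2.14 ± 0.12, and FOS by 2.21 ± 0.14, at least 3.52-fold. Of 24 members, 18 rose and 1 fell (19 and 1 over the list alone), with a median of 1.03 and a camera adjusted p of 2.2e-28. Among targets of TGF-beta, BMP and YAP, ID1 and ID3, inhibitors of basic helix-loop-helix factors, rose by 2.15 ± 0.10 and 1.31 ± 0.07, and SMAD7, an inhibitor of TGF-beta signalling, by 1.87 ± 0.09. Of 14 members, 10 rose and 0 fell (11 and 0 over the list alone), with a median of 0.85 and a camera adjusted p of 1.2e-20.

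Smaller shifts of the same comparison passed in 4 more lists. The immediate early list also holds GADD45B (p53), IER3 (NF-kB), JUN and IER5 (chaperones) and KLF10 (TGF-beta), so calls of these lists are not independent. Of 19 p53 targets and growth arrest genes, 6 rose and 2 fell, among them GADD45B at 1.54 ± 0.20 and GADD45A at 0.79 ± 0.12, with a camera adjusted p of 0.00747. Of 20 replication-dependent histone genes 3 rose and 0 fell (6 and 0 over the list alone), with H2AC18 at 0.92 ± 0.10, a median of 0.14 and a camera adjusted p of 0.00401, against an adjusted p of 0.201 with an estimated correlation. Of 20 genes of the ATF4 and amino acid response 4 rose and 1 fell, with DDIT4, an inhibitor of mTORC1, at 2.67 ± 0.10 and a camera adjusted p of 0.00747, against an adjusted p of 0.0988 with an estimated correlation. Of 7 NF-kB and cytokine genes 3 rose and 0 fell, with IER3 at 1.03 ± 0.12 and a camera adjusted p of 0.0326, against an adjusted p of 0.0813 with an estimated correlation. The NF-kB call was lost without scrambled untreated replicate 1 (adjusted p = 0.102, camera) or 4 (adjusted p = 0.0502). The medians of the ATF4, p53 and NF-kB lists were 0.05, 0.10 and 0.11, and with median scaling they turned to -0.0036, -0.0039 and -0.0028, while the histone median was 0.050. The ATF4, p53, NF-kB and histone calls held with that scaling (camera, adjusted p = 0.00170, 0.00117, 0.0365 and 0.00170), where the median of all genes fell as well. Single arrays moved the list medians too. The ATF4 median was 0.035 without heat shock replicate 2, the p53 median 0.16 without heat shock replicate 1 and 0.15 without untreated replicate 3, and the NF-kB median 0.18 without untreated replicate 2 or heat shock replicate 4 and 0.06 without heat shock replicate 3. The splicing kinase genes CLK1 and CLK4 rose by 1.46 ± 0.09 and 0.83 ± 0.10, while the 25 SR protein and CLK kinase genes as a list did not pass (camera, adjusted p = 0.355).

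Among the falls, the largest by rule was TERC, the RNA component of telomerase, at -2.64 ± 0.16, or 6.25-fold. RSRP1, coding for a protein rich in arginine and serine, fell by 2.20 ± 0.08, at least 2.47-fold. SCARNA9, a small Cajal body RNA, fell by 1.31 ± 0.11, CCDC71 at -1.31 ± 0.09 and FJX1 at -1.01 ± 0.10. The heterochromatin and centromere genes CENPB and SUV39H1 fell by 0.51 ± 0.07 and 0.44 ± 0.07.

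In all, 1184 genes passed with limma, 606 higher and 578 lower, of which 207 and 96 changed at least 1.5-fold and 74 and 7 at least 2-fold. With the batch of replicates 1 and 2 against 3 and 4 as a block 1345 genes passed, with replicates 1 and 2 alone 567, and with replicates 3 and 4 alone 261. List medians within the batches were 0.70 and 0.38 for chaperones, 1.10 and 0.84 for immediate early genes, 0.95 and 0.83 for TGF-beta, BMP and YAP targets, 0.13 and 0.13 for p53 targets, and 0.17 and 0.16 for histones. For the ATF4 list they were 0.07 (camera, adjusted p = 0.0666) and 0.10, and for the NF-kB list 0.19 (adjusted p = 0.0666) and 0.20 (adjusted p = 0.0601). With median scaling 251 genes passed, without GADD45A and SUV39H1, and the median of all genes was -0.119.

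After 6 h of recovery, scrambled-siRNA cells still held high chaperone levels compared with untreated cells. HSPA6 was higher by 5.52 ± 0.24, at least 30.2-fold (limma, adjusted p = 1.2e-12, 4 against 4 arrays). SERPINH1, the collagen chaperone HSP47, was higher by 2.69 ± 0.12, or 6.44-fold, HSPH1 by 2.02 ± 0.10, or 4.06-fold, and HSPB1, which codes for the small heat shock protein HSP27, by 2.00 ± 0.12. The small heat shock protein genes CRYAB and HSPB8 were higher by 2.22 ± 0.25 (at least 2.39-fold) and 1.15 ± 0.16 (at least 1.70-fold), and HSPA4L 2.83-fold. DNAJB1 stood at 0.75 ± 0.09. The uncertain copies HSPA1A and HSPA1B were at 1.45 ± 0.33 (at least 1.37-fold) and 0.36 ± 0.07. Of the 40 chaperones and HSF1 targets 20 rose and 1 fell (21 and 3 over the list alone), with a median of 0.38 and a camera adjusted p of 4.6e-17.

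Genes of cholesterol synthesis fell in recovery. Of 16 tested members 0 rose and 12 fell (12 also over the list alone), with a median of -0.49 and a camera adjusted p of 1.2e-09. IDI1, an isomerase of the pathway, fell by 0.88 ± 0.19, INSIG1, a regulator of sterol sensing, at -0.64 ± 0.09, SQLE, a rate-limiting epoxidase, at -0.63 ± 0.10, and HMGCS1 at -0.53 ± 0.09. Of 27 nuclear stress body and hnRNP genes 0 rose and 5 fell (7 over the list alone), with SAFB2 at -0.51 ± 0.08 and HNRNPU at -0.42 ± 0.09. That list had a median of -0.14 and a camera adjusted p of 0.00140, against an adjusted p of 0.110 with an estimated correlation. Of 33 ribosome biogenesis genes and MYC targets 1 rose and 6 fell (1 and 10 over the list alone), with NOP14 at -0.45 ± 0.09, a median of -0.12 and a camera adjusted p of 0.00140. With median scaling the nuclear stress body and ribosome biogenesis medians were -0.27 and -0.24. Other falls were TERC at -1.36 ± 0.16, OGDH, an enzyme of the citric acid cycle, at -0.93 ± 0.11, SULF1 at -0.86 ± 0.10 and CSPG5 at -0.82 ± 0.08.

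HSPA5, which codes for the chaperone BiP of the endoplasmic reticulum, rose by 0.78 ± 0.09, or 1.72-fold. Of 19 endoplasmic reticulum stress genes 5 rose and 0 fell (7 and 0 over the list alone), with a median of 0.10 and a camera adjusted p of 0.00104, against an adjusted p of 0.121 with an estimated correlation. Of 20 ATF4 and amino acid genes 7 rose and 1 fell (9 and 1 over the list alone), with a median of 0.13 and a camera adjusted p of 4.7e-05. Among them PSAT1, of serine synthesis, rose by 0.55 ± 0.09, SLC7A5, a leucine transporter gene, by 0.49 ± 0.08, and ASNS, asparagine synthetase, by 0.42 ± 0.07. Of 47 G2/M and mitosis genes 6 rose and 0 fell (10 and 0 over the list alone), with CDC20 at 0.30 ± 0.06, a median of 0.09 and a camera adjusted p of 0.00579. With median scaling the G2/M median turned to -0.03 and the call was lost (camera, adjusted p = 0.25), and the median of the endoplasmic reticulum list turned to -0.0039, while that of the ATF4 list was 0.022. The endoplasmic reticulum and ATF4 calls held with that scaling (camera, adjusted p = 0.0216 and 0.000925). The endoplasmic reticulum median was 0.17, 0.18, 0.06 and 0.04 without untreated replicate 1, 2, 3 or 4, and 0.06, 0.17 and 0.17 without recovery replicate 1, 2 or 4, and the G2/M median was 0.06 without recovery replicate 2.

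Immediate early genes had a median of 0.21, with 2 of 24 higher and 2 lower (4 and 2 over the list alone), a camera adjusted p of 0.00891 and an adjusted p of 0.302 with an estimated correlation. PPP1R15A, a phosphatase subunit gene of the stress response, rose by 0.51 ± 0.10 and EGR3, an early growth response factor gene, fell by 0.64 ± 0.16, at least 1.20-fold. TGF-beta, BMP and YAP targets had a median of 0.11, with 3 of 14 higher and 0 lower (4 and 0 over the list alone), a camera adjusted p of 0.0324 and an adjusted p of 0.296 with an estimated correlation. Without scrambled untreated replicate 2 the calls of these lists were lost, at adjusted p = 0.0540 and adjusted p = 0.133 with camera, and the TGF-beta call also without scrambled recovery replicate 3 (0.0593) or 4 (0.0685). The TGF-beta median was 0.06 without untreated replicate 2, 0.05 without recovery replicate 3 and 0.021 with median scaling.

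The epithelial surface marker EPCAM, from the list of keratinocyte and cervical carcinoma markers, was higher by 0.59 ± 0.09 in recovering than in untreated scrambled-siRNA cells (limma, adjusted p = 1.9e-04). In this comparison 1106 genes passed with limma, 599 higher and 507 lower, 101 and 42 of them at least 1.5-fold and 15 and 1 at least 2-fold. The count was 1405 with the batch as a block, 165 with replicates 1 and 2 alone, 76 with replicates 3 and 4 alone, 508 when only the 2 groups were fitted and 45 with median scaling. Median scaling ended the calls of DNAJB1, HSPA1B, HSPA5, PPP1R15A, EGR3, PSAT1, SLC7A5, ASNS, CDC20, IDI1, INSIG1, SQLE, HMGCS1, SAFB2, HNRNPU, NOP14 and EPCAM, fitting only the 2 groups those of CDC20 and HNRNPU, the mean of probes that of HNRNPU, and the authors' values on the 15 matching arrays that of EGR3. Within the batches, list medians were 0.34 and 0.40 for chaperones, -0.38 and -0.45 for cholesterol, 0.17 and 0.17 for ATF4, -0.16 and -0.17 for nuclear stress body, -0.13 and -0.12 for ribosome biogenesis, and 0.25 and 0.20 for immediate early genes. In replicates 1 and 2 the call was lost for endoplasmic reticulum stress (0.11, camera adjusted p = 0.0610), G2/M (0.06, 0.0610) and TGF-beta targets (0.09, 0.0661), and in replicates 3 and 4 their medians were 0.22, 0.10 and 0.13.

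Recovery was then set directly against heat shock in the scrambled arm. DNAJB1 fell by 3.67 ± 0.09, or 12.7-fold (limma, adjusted p = 9.8e-18, 4 against 4 arrays), HSPA6 at -2.87 ± 0.24, DUSP1 at -3.09 ± 0.13, JUN at -2.69 ± 0.09 and DDIT4 at -2.40 ± 0.10. RPPH1, the RNA of ribonuclease P, fell by 2.48 ± 0.28. HSPH1 rose further, by 0.56 ± 0.10. RSRP1 rose by 2.69 ± 0.08, at least 3.48-fold, CRYAB by 1.39 ± 0.25, FJX1 by 1.37 ± 0.10 and EMILIN2, an extracellular matrix gene, by 1.36 ± 0.12. DHRS2, a short-chain dehydrogenase gene, rose by 1.48 ± 0.15, at least 2.25-fold. EPCAM was higher by 0.70 ± 0.09 in recovering cells.

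Immediate early genes fell, with 17 of 24 lower and 1 higher (18 and 1 over the list alone), a median of -0.85 and a camera adjusted p of 4.2e-16. TGF-beta, BMP and YAP targets fell with 9 of 14 lower and 0 higher (10 and 0 over the list alone), a median of -0.66 and a camera adjusted p of 2.7e-11, among them ID1 at -1.98 ± 0.10. Cholesterol synthesis genes fell with 12 of 16 lower and 0 higher (12 also over the list alone), a median of -0.51 and a camera adjusted p of 8.6e-09, with INSIG1 at -1.07 ± 0.09 and MSMO1 at -1.05 ± 0.12. G2/M and mitosis genes rose with 13 of 47 higher and 0 lower (19 and 0 over the list alone), a median of 0.20 and a camera adjusted p of 0.000158. KIF23 and TTK, a mitotic kinesin and a spindle checkpoint kinase gene, rose by 0.41 ± 0.09 and 0.39 ± 0.07.

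Of the 40 chaperones and HSF1 targets 7 rose and 15 fell (8 and 15 over the list alone), with a median of -0.09 and a camera adjusted p of 0.00104, against an adjusted p of 0.291 with an estimated correlation. Of 19 endoplasmic reticulum stress genes 6 rose and 1 fell (8 and 1 over the list alone), with HSPA5 at 1.14 ± 0.09, a median of 0.16 and a camera adjusted p of 0.00285, against an adjusted p of 0.207 with an estimated correlation. Of 20 histone genes 0 rose and 6 fell (6 also over the list alone), with H2BC21 at -0.59 ± 0.13 (at least 1.02-fold), a median of -0.19 and a camera adjusted p of 0.0119, against an adjusted p of 0.291 with an estimated correlation. Of 33 ribosome biogenesis genes 2 rose and 4 fell (2 and 4 over the list alone), with POLR1B at -0.59 ± 0.11, a median of -0.11 and a camera adjusted p of 0.0261, against an adjusted p of 0.0666 with an estimated correlation. That call was lost without scrambled heat shock replicate 3 (camera, adjusted p = 0.0562), and the chaperone median was -0.06 without heat shock replicate 4. CLK1 and CLK4 fell by 1.56 ± 0.09 and 0.94 ± 0.10, within a list of 25 SR protein and CLK kinase genes that did not pass (camera, adjusted p = 0.342).

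In total 2202 genes passed with limma, 1235 higher and 967 lower, 279 and 195 of them at least 1.5-fold and 26 and 60 at least 2-fold. The count was 2492 with the batch as a block, 1020 with replicates 1 and 2 alone, 583 with replicates 3 and 4 alone and 457 with median scaling, where 67.0% of the calls were higher against 56.1% in the main analysis. The calls of HSPH1, KIF23, TTK, H2BC21 and POLR1B were lost with median scaling, and that of KIF23 also with the mean of probes. List medians within the batches were -0.98 and -0.78 for immediate early genes, -0.72 and -0.59 for TGF-beta targets, -0.48 and -0.52 for cholesterol, 0.18 and 0.22 for G2/M, -0.09 and -0.09 for chaperones, and 0.24 and 0.13 for endoplasmic reticulum stress. In replicates 1 and 2 the histone median was -0.08 (camera, adjusted p = 0.236) and the ribosome biogenesis median -0.09 (adjusted p = 0.0700), and in replicates 3 and 4 they were -0.30 and -0.13.

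In cells with Sat III siRNA the heat shock response was measured in the same way, with 3 against 3 arrays. HSPA6 rose by 8.67 ± 0.27, at least 233-fold (limma, adjusted p = 9.4e-16), DNAJB1 by 4.41 ± 0.10, or 21.2-fold, BAG3 by 2.45 ± 0.11 and HSPH1 by 1.65 ± 0.12, or 3.13-fold. The uncertain copies HSPA1A and HSPA1B rose by 3.55 ± 0.38 (at least 5.78-fold) and 1.89 ± 0.08. Of the 40 chaperones and HSF1 targets 20 rose and 0 fell (26 and 0 over the list alone), with a median of 0.47 and a camera adjusted p of 3.4e-35. DUSP1 rose by 3.61 ± 0.15, JUN by 3.06 ± 0.10, ATF3 by 2.59 ± 0.14 and PPP1R15A by 2.37 ± 0.11. Of 24 immediate early genes 16 rose and 1 fell (17 and 1 over the list alone), with a median of 0.95 and a camera adjusted p of 2.5e-29. ID1, SMAD7 and HES1, a Notch and BMP target, rose by 2.14 ± 0.11, 1.82 ± 0.10 and 2.04 ± 0.12. Of 14 TGF-beta, BMP and YAP targets 10 rose and 0 fell (10 and 1 over the list alone), with a median of 0.95 and a camera adjusted p of 3.8e-20.

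Of 19 p53 targets and growth arrest genes 6 rose and 0 fell, also over the list alone, with GADD45B at 1.54 ± 0.23, a median of 0.15 and a camera adjusted p of 0.00127. The median was 0.10 without untreated replicate 1 and 0.05 without heat shock replicate 4, and 0.063 with median scaling. TXNIP, a thioredoxin-binding protein gene, rose by 2.29 ± 0.19 and RNU6ATAC, a small RNA of the minor spliceosome, by 2.48 ± 0.44, at least 4.32-fold. TERC fell by 2.60 ± 0.19, RSRP1 at -2.08 ± 0.09, at least 2.31-fold, MYC at -1.10 ± 0.15, UFSP1 at -1.37 ± 0.17 and SNORA33, a small nucleolar RNA, at -1.34 ± 0.10. CD14, a marker of monocytes, rose by 0.96 ± 0.20 (limma, adjusted p = 0.00231) from a low signal, with a mean of 5.65 over all arrays. CD14 did not pass without the arrays of replicate 1 (limma, adjusted p = 0.140) or of replicate 2 (0.0767), and stood at 0.43 with replicates 3 and 4 alone.

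Another 3 lists passed, and each call rested on single arrays. Of 20 histone genes 3 rose and 0 fell (5 and 0 over the list alone), with H2AC18 at 1.12 ± 0.11, a median of 0.04 and a camera adjusted p of 0.0216, against an adjusted p of 0.327 with an estimated correlation. With median scaling the histone median was -0.02 and the call held (camera, adjusted p = 0.0135). Without Sat III siRNA untreated replicate 2 the median was -0.03 and the call was lost (camera, adjusted p = 0.161), as it was without heat shock replicate 4 (0.01, adjusted p = 0.188). That median was 0.09 and 0.07 without heat shock replicate 1 or 2 and 0.12 without untreated replicate 4. Of 13 interferon response genes 3 rose and 0 fell, also over the list alone, with IFI35 at 0.69 ± 0.15, a median of 0.16 (0.058 with median scaling) and a camera adjusted p of 0.0216, against an adjusted p of 0.0574 with an estimated correlation. It was lost without Sat III siRNA untreated replicate 2 (camera, adjusted p = 0.0817) or heat shock replicate 2 (0.0594). Of 7 NF-kB and cytokine genes 3 rose and 0 fell, also over the list alone, with IER3 at 1.43 ± 0.14, a median of 0.01 (-0.09 with median scaling, where the call held at a camera adjusted p of 0.0145) and a camera adjusted p of 0.0257, against an adjusted p of 0.0574 with an estimated correlation. It was lost without Sat III siRNA heat shock replicate 2 (camera, adjusted p = 0.0594) or untreated replicate 4 (0.0714). Its median was -0.0021, 0.04 and 0.05 without heat shock replicate 1, 2 or 4, and 0.06 and 0.03 without untreated replicate 1 or 4.

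With limma 773 genes passed, 417 higher and 356 lower, 206 and 90 of them at least 1.5-fold and 78 and 12 at least 2-fold. The count was 918 with the batch as a block, 470 with replicates 1 and 2 alone, 68 with replicates 3 and 4 alone (1 array per group) and 157 with median scaling, where 65.6% of the calls were higher against 53.9% and IFI35 did not pass. The scrambled and Sat III siRNA arms shared 343 of their higher genes, where 24.9 would be shared by independent lists, and 240 of their lower genes, against 20.3, and their log2 fold changes correlated at r = 0.806 over all genes. The arms share a common estimate of the spread of each gene, so their lists are not fully independent. Within the batches, list medians were 0.53 and 0.37 for chaperones, 1.15 and 0.58 for immediate early genes, 1.03 and 0.79 for TGF-beta targets and 0.14 and 0.18 for p53 targets. For histones they were 0.05 (camera, adjusted p = 0.135) and 0.13, for the interferon list 0.22 and 0.18 (adjusted p = 0.182) and for the NF-kB list 0.07 (adjusted p = 0.0921) and 0.07.

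Recovering Sat III siRNA cells were compared with untreated ones of the same arm, with 4 against 3 arrays. HSPA6 was higher by 5.08 ± 0.26, at least 19.3-fold (limma, adjusted p = 1.5e-11), SERPINH1 by 3.02 ± 0.13, or 8.12-fold, HSPB1 by 2.00 ± 0.12, CRYAB by 2.11 ± 0.27, at least 2.21-fold, HSPA4L by 1.34 ± 0.09 and HSPH1 by 1.33 ± 0.11, or 2.51-fold. HSPA5 rose by 1.25 ± 0.09, or 2.37-fold. DNAJB1 did not pass at 0.23 ± 0.10, nor did HSPA1B, an uncertain copy, at -0.15 ± 0.08 (limma, adjusted p = 0.14 and 0.23). Of the 40 chaperones and HSF1 targets 17 rose and 3 fell (21 and 4 over the list alone), with a median of 0.33 (0.20 with median scaling) and a camera adjusted p of 3.7e-10, against an adjusted p of 0.0671 with an estimated correlation.

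Of 16 cholesterol synthesis genes 0 rose and 8 fell (12 over the list alone), with INSIG1 at -1.03 ± 0.10, HMGCS1 at -0.94 ± 0.09, a median of -0.36 and a camera adjusted p of 2.8e-09. Of 19 endoplasmic reticulum stress genes 5 rose and 0 fell (6 and 0 over the list alone), with HSP90B1 at 0.37 ± 0.08, a median of 0.18 and a camera adjusted p of 0.000834, against an adjusted p of 0.156 with an estimated correlation. Of 27 nuclear stress body and hnRNP genes 0 rose and 5 fell (8 over the list alone), with SAFB2 at -0.45 ± 0.09, a median of -0.11 and a camera adjusted p of 0.00566, against an adjusted p of 0.156 with an estimated correlation. Of 47 G2/M genes 4 rose and 0 fell, also over the list alone, with CENPF, a kinetochore protein gene, at 0.49 ± 0.10, a median of 0.10 and a camera adjusted p of 0.00760, against an adjusted p of 0.0671 with an estimated correlation. Of 20 ATF4 and amino acid genes 6 rose and 1 fell (8 and 1 over the list alone), with SLC3A2 at 0.60 ± 0.12, a median of 0.13 and a camera adjusted p of 0.0260, against an adjusted p of 0.156 with an estimated correlation. With median scaling the G2/M and ATF4 medians turned to -0.01 and -0.0027 and the calls were lost (camera, adjusted p = 0.278 and 0.155), while the endoplasmic reticulum and nuclear stress body medians were 0.024 and -0.28. The ATF4 call was also lost without Sat III siRNA untreated replicate 2 (0.0758) or recovery replicate 4 (0.0523). CCND1, coding for cyclin D1, fell by 0.47 ± 0.07, CA8 at -1.06 ± 0.17 and TERC at -0.88 ± 0.18. EPCAM was higher by 0.62 ± 0.10 in recovering cells.

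With limma 1217 genes passed, 614 higher and 603 lower, 122 and 73 of them at least 1.5-fold and 19 and 5 at least 2-fold. The count was 635 without Sat III siRNA untreated replicate 1, 740 without replicate 2 and 770 without replicate 4. It was 1471 with the batch as a block, 238 with replicates 1 and 2 alone, 15 with replicates 3 and 4 alone and 43 with median scaling, which ended the calls of CENPF, HSP90B1, SLC3A2, SAFB2, CCND1, TERC and EPCAM. CENPF and HSP90B1 also did not pass with the authors' values on the 15 matching arrays. The 2 arms, which share a common estimate of the spread of each gene, had 334 higher genes in common, against 36.2 for independent lists, and 292 lower genes, against 30.1, and r over all genes was 0.741. List medians within the batches were 0.37 and 0.28 for chaperones, -0.37 and -0.51 for cholesterol, 0.19 and 0.18 for endoplasmic reticulum stress and -0.10 and -0.10 for nuclear stress body genes. For G2/M they were 0.10 (camera, adjusted p = 0.0545) and 0.12, and for ATF4 0.11 (adjusted p = 0.153) and 0.15 (adjusted p = 0.147).

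Between heat shock and recovery in the Sat III siRNA arm, with 4 against 3 arrays, DNAJB1 fell by 4.18 ± 0.10, or 18.1-fold (limma, adjusted p = 3.2e-18), HSPA6 at -3.60 ± 0.26, or 12.1-fold, DUSP1 at -3.58 ± 0.14, JUN at -2.97 ± 0.09, ATF3 at -2.67 ± 0.13 and DDIT4 at -2.49 ± 0.11. RSRP1 rose by 2.72 ± 0.09, at least 3.60-fold, and TERC by 1.71 ± 0.18. Of the 40 chaperones and HSF1 targets 5 rose and 16 fell (8 and 17 over the list alone), with a median of -0.12 and a camera adjusted p of 7.1e-05, against an adjusted p of 0.244 with an estimated correlation. Of 24 immediate early genes 1 rose and 18 fell, also over the list alone, with a median of -1.01 and a camera adjusted p of 7.3e-17. Of 14 TGF-beta, BMP and YAP targets 0 rose and 10 fell (1 and 10 over the list alone), with a median of -0.58 and a camera adjusted p of 1.9e-10. Of 16 cholesterol synthesis genes 0 rose and 12 fell, also over the list alone, with INSIG1 at -1.21 ± 0.10 and HMGCS1 at -1.16 ± 0.09, a median of -0.45 and a camera adjusted p of 2.7e-09. Of 47 G2/M genes 17 rose and 2 fell, also over the list alone, with TTK at 0.51 ± 0.08 and KIF2C at 0.47 ± 0.08, a median of 0.12 and a camera adjusted p of 0.00140.

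Of 19 endoplasmic reticulum stress genes 6 rose and 1 fell (7 and 1 over the list alone), with HSPA5 at 1.29 ± 0.09, a median of 0.23 and a camera adjusted p of 0.0417, against an adjusted p of 0.377 with an estimated correlation. That call was lost without Sat III siRNA heat shock replicate 1 (camera, adjusted p = 0.0536) or 2 (0.0804, with a median of 0.15) and without recovery replicate 1 (0.117). With median scaling the endoplasmic reticulum median was 0.15, and the endoplasmic reticulum and G2/M calls were lost (camera, adjusted p = 0.159 and 0.0990). EPCAM was higher by 0.62 ± 0.10 and the fibroblast marker LUM by 0.42 ± 0.14 in recovering than in heat-shocked cells, and CD14 was lower, at -0.90 ± 0.18. LUM did not pass without recovery replicate 1 (limma, adjusted p = 0.0667) or 2 (0.0744) or without heat shock replicate 2 (0.199) or 4 (0.0572), and CD14 did not pass without the arrays of replicate 1 (0.0587).

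With limma 2182 genes passed, 1193 higher and 989 lower, 324 and 242 of them at least 1.5-fold and 41 and 81 at least 2-fold. The count was 2449 with the batch as a block, 1122 with replicates 1 and 2 alone, 342 with replicates 3 and 4 alone and 414 with median scaling, which ended the calls of TTK, KIF2C, EPCAM and LUM. Within the batches, list medians were -1.08 and -0.69 for immediate early genes, -0.62 and -0.47 for TGF-beta targets, -0.53 and -0.42 for cholesterol, -0.12 and -0.09 for chaperones, 0.12 and 0.14 for G2/M, and 0.25 and 0.14 for endoplasmic reticulum stress, the last with an adjusted p of 0.274 by camera.

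Sat III siRNA was next compared with scrambled siRNA within each treatment, first in untreated cells, with 3 against 4 arrays. TMEM64, a membrane protein gene, was higher by 1.32 ± 0.08 (limma, adjusted p = 1.6e-09), RNF149, a ubiquitin ligase gene, by 0.90 ± 0.09, and FYCO1 and GUF1 by 0.71. TRAK2, a kinesin adaptor gene for mitochondrial transport, was lower by 1.52 ± 0.09, or 2.88-fold, EXOSC5, a subunit of the RNA exosome, at -1.25 ± 0.10, SERP1 at -1.24 ± 0.13, the choline transporter gene SLC44A1 at -1.20 ± 0.10, and GNG4, a G protein gamma subunit gene, at -1.06 ± 0.12. ACTA2, smooth muscle actin, was lower by 1.02 ± 0.10, and CCND1 at -0.70 ± 0.07 (limma, adjusted p = 2.7e-06). LCP1, an actin-bundling protein gene listed as a marker of blood cells, was lower by 0.84 ± 0.06 with a mean signal of 11.1 over all arrays. The chaperone genes DNAJB1 and HSPH1 did not pass, at 0.03 ± 0.10 and -0.24 ± 0.11, nor did the uncertain copy HSPA1B at 0.04 ± 0.08. Camera called 0 of the 25 lists in untreated cells, and the smallest adjusted p was 0.0573, for ribosome biogenesis with a median of 0.10. At an unadjusted p under 0.05 camera found 3 lists, with an estimated correlation it called 0, and fry, which tests lists against no change, called 8.

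In this comparison 618 genes passed with limma, 230 higher and 388 lower, 24 and 113 of them at least 1.5-fold and 1 and 13 at least 2-fold. The count was 374 without Sat III siRNA untreated replicate 1, 408 without replicate 2 and 383 without replicate 4. It was 809 with the batch as a block, 193 with replicates 1 and 2 alone, 9 with replicates 3 and 4 alone, 309 when only the 2 groups were fitted, 973 with array weights and 44 with median scaling, where 6.82% of the calls were higher against 37.2% and RNF149, FYCO1, GUF1 and CCND1 did not pass.

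In heat-shocked cells, with 3 against 4 arrays, TMEM64 was higher by 1.23 ± 0.08 and RNF149 by 0.90 ± 0.09, and SLC40A1, the iron exporter ferroportin, by 1.01 ± 0.11, at least 1.46-fold. EXOSC5 was lower by 1.67 ± 0.10, or 3.18-fold (limma, adjusted p = 1.7e-09), TRAK2 at -1.35 ± 0.09, SLC11A2, an iron transporter gene, at -1.29 ± 0.08, and NAP1L1, a histone chaperone gene, at -1.26 ± 0.10. CCND1 was lower by 0.82 ± 0.07, GINS2, of the replicative helicase, at -0.73 ± 0.07 and LCP1 at -0.88 ± 0.06. DNAJB1, HSPH1 and the uncertain copy HSPA1B did not pass, at 0.02, -0.06 and -0.02.

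In heat-shocked cells 4 lists passed. Of 20 ATF4 and amino acid genes 0 rose and 1 fell (5 over the list alone), with ATF5 at -0.46 ± 0.09, a median of -0.12 and a camera adjusted p of 0.0213, against an adjusted p of 0.210 with an estimated correlation. Of 33 ribosome biogenesis genes 2 rose and 0 fell, also over the list alone, with a median of 0.07 and a camera adjusted p of 0.0229, against an adjusted p of 0.116 with an estimated correlation. Of 41 G1/S and DNA replication genes 2 rose and 3 fell (2 and 4 over the list alone), with a median of -0.07 and a camera adjusted p of 0.0312, against an adjusted p of 0.239 with an estimated correlation. Of 11 genes of the RNA interference machinery 1 rose and 0 fell (2 and 0 over the list alone), with AGO1 at 0.37 ± 0.07, a median of 0.14 and a camera adjusted p of 0.0348, against an adjusted p of 0.427 with an estimated correlation. With median scaling the ATF4, G1/S and RNA interference calls were lost (camera, adjusted p = 0.111, 0.184 and 0.0871). Without heat shock replicate 1 of the scrambled or the Sat III siRNA arm the G1/S call was lost (0.0503 and 0.104), as was the RNA interference call (0.0717 and 0.145), which was also lost without heat shock replicate 4 of either arm (0.0822 and 0.0651). The RNA interference median was 0.07 without Sat III siRNA heat shock replicate 1, and the ribosome biogenesis median 0.11 without Sat III siRNA heat shock replicate 2 and 0.05 without scrambled heat shock replicate 4.

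With limma 713 genes passed in heat-shocked cells, 238 higher and 475 lower, 29 and 146 of them at least 1.5-fold and 2 and 17 at least 2-fold. The count was 434 without Sat III siRNA heat shock replicate 2. It was 852 with the batch as a block, 250 with replicates 1 and 2 alone, 37 with replicates 3 and 4 alone and 68 with median scaling, where 14.7% of the calls were higher against 33.4% and ATF5, AGO1 and GINS2 did not pass. AGO1 also did not pass with the authors' values on the 15 matching arrays. List medians in replicates 1 and 2 and in replicates 3 and 4 were -0.14 and -0.10 for ATF4 (camera, adjusted p = 0.143 in the latter) and -0.09 and -0.04 for G1/S (0.291 in the latter). They were 0.07 and 0.11 for ribosome biogenesis (0.0908 and 0.123) and 0.14 and 0.11 for RNA interference (0.120 and 0.126).

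In recovering cells, with 4 against 4 arrays, Sat III siRNA went with lower levels of several chaperone genes. HSPH1 was lower by 0.93 ± 0.10, or 1.91-fold (limma, adjusted p = 1.4e-06), DNAJB1 at -0.49 ± 0.09 and the uncertain copy HSPA1B at -0.46 ± 0.07. HSPA6 did not pass at -0.58 ± 0.24 (adjusted p = 0.136). Of the 40 chaperones and HSF1 targets 1 was higher and 6 were lower, and the list did not pass (camera, adjusted p = 0.376). ATF3 was lower by 0.97 ± 0.12. TRAK2 was lower by 1.77 ± 0.09, or 3.41-fold, GNG4 at -1.68 ± 0.11, SERP1 at -1.54 ± 0.12, EXOSC5 at -1.43 ± 0.10, ACTA2 at -1.39 ± 0.10, SLC44A1 at -1.34 ± 0.10, CCND1 at -0.88 ± 0.07 and LCP1 at -0.79 ± 0.06, while TMEM64 was higher by 1.34 ± 0.08.

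Of 33 ribosome biogenesis genes and MYC targets 6 rose and 0 fell (9 and 0 over the list alone), with PPAN at 0.45 ± 0.10 and BYSL at 0.29 ± 0.07, factors of ribosomal subunit assembly. The list's median was 0.14 and camera's adjusted p was 0.000653. Of 20 ATF4 and amino acid genes 0 rose and 7 fell (9 over the list alone), with SESN2, a leucine sensor of the mTORC1 pathway, at -0.54 ± 0.12, a median of -0.21 and a camera adjusted p of 0.00154, against an adjusted p of 0.0606 with an estimated correlation. Of 36 mitochondrial respiration genes 2 rose and 0 fell (1 and 0 over the list alone), with NDUFB2, of complex I, at 0.34 ± 0.07, a median of 0.07 and a camera adjusted p of 0.0173. That call was lost without Sat III siRNA recovery replicate 1 (camera, adjusted p = 0.0569) or 2 (0.0571).

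With limma 1067 genes passed in recovering cells, 365 higher and 702 lower, 36 and 153 of them at least 1.5-fold and 1 and 27 at least 2-fold. The count was 1305 with the batch as a block, 293 with replicates 1 and 2 alone, 151 with replicates 3 and 4 alone, 710 when only the 2 groups were fitted and 114 with median scaling, where 4.39% of the calls were higher against 34.2% and DNAJB1, HSPA1B, PPAN, BYSL, SESN2 and NDUFB2 did not pass. BYSL also did not pass when only the 2 groups were fitted, nor did BYSL and PPAN with the authors' values on the 15 matching arrays. List medians within the batches were 0.16 and 0.15 for ribosome biogenesis, -0.21 and -0.15 for ATF4, and 0.10 and 0.07 for mitochondrial respiration, the last with an adjusted p of 0.174 by camera.

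The siRNA effect was compared between treatments, which share no arrays but do share a common estimate of the spread of each gene. Genes with a small spread pass more easily in each comparison. Some overlap beyond that of independent lists therefore comes without a shared effect. In all 3 treatments 335 genes passed in the same direction, 93 higher and 242 lower. Untreated and heat-shocked cells shared 114 higher and 259 lower genes, where independent lists would share 5.39 and 18.2. Untreated and recovering cells shared 145 and 303, against 8.27 and 26.8, and heat-shocked and recovering cells 137 and 354, against 8.56 and 32.9. The log2 fold changes of all genes correlated at r = 0.648, 0.688 and 0.725 for these pairs, and 0 genes passed in opposite directions in any pair.

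**Figure D2:**
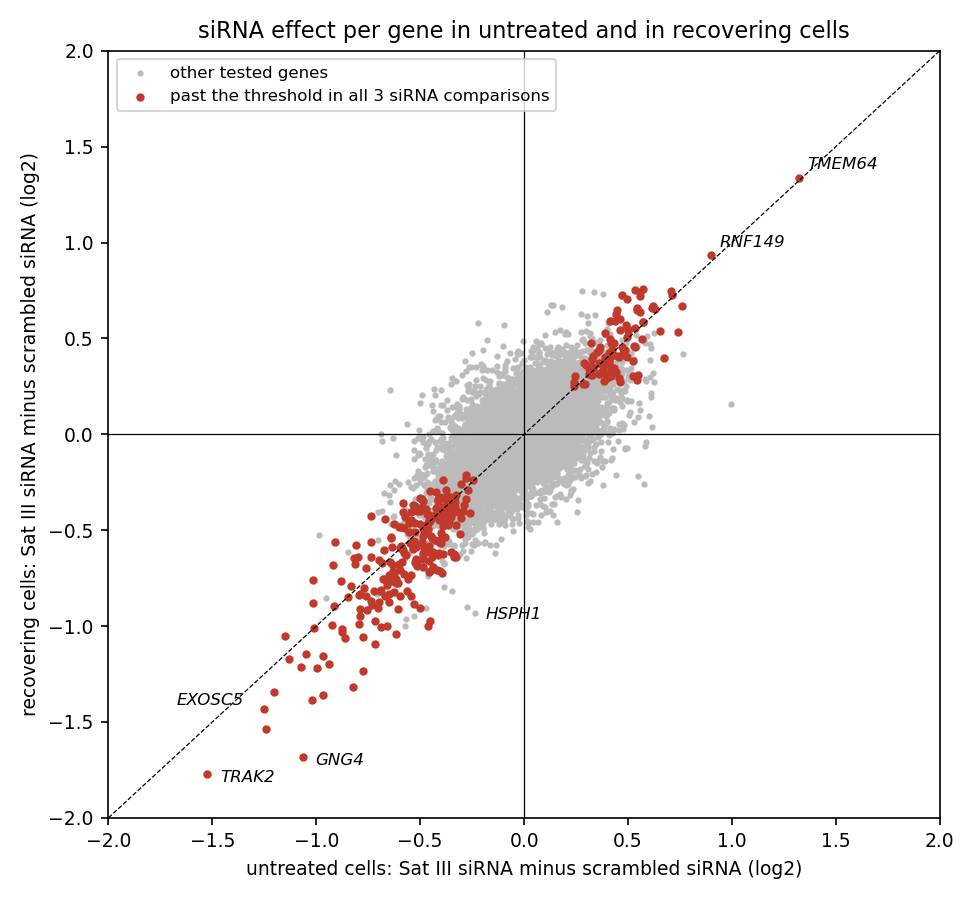
Log2 difference between Sat III siRNA and scrambled siRNA for each gene in untreated cells (horizontal axis) and in recovering cells (vertical axis), with the 335 genes that passed in all 3 treatments in red. TMEM64 lies at 1.32 and 1.34 and TRAK2 at -1.52 and -1.77, while HSPH1 lies at -0.24 and -0.93.

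The interaction terms asked whether Sat III siRNA altered the response itself. For heat shock, 0 genes passed with limma, 368 had an unadjusted p under 0.05 and the smallest adjusted p was 0.415. The 6 genes with the smallest p did not pass and were NAA60 (-0.997 ± 0.19), ZNF747 (-1.07 ± 0.25), C19orf73 (-0.84 ± 0.21), CAMKK1 (-0.63 ± 0.15), GAB2 (0.52 ± 0.12) and SERTAD2 (0.47 ± 0.11). With the batch as a block and within each batch the count was also 0, and without Sat III siRNA heat shock replicate 4 it was 2. Camera called 0 of the 25 lists for heat shock, with 3 at an unadjusted p under 0.05, and camera with an estimated correlation called 0, as did fry, against no change.

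For recovery, 0 genes passed with limma, 387 had an unadjusted p under 0.05 and the smallest adjusted p was 0.640. The 6 genes with the smallest p did not pass and were HSPH1 (-0.69 ± 0.15), the uncertain copy HSPA1B (-0.50 ± 0.10), PPIAL4A (-0.54 ± 0.12), NSUN3 (-0.66 ± 0.15), BARX1 (-0.56 ± 0.14) and C3orf70 (-0.52 ± 0.13). DNAJB1 stood at -0.52 ± 0.13 (limma, adjusted p = 0.860). With the batch as a block and within each batch the count was also 0, and with a variance trend and robust prior it was 1. The 40 chaperones and HSF1 targets had a median interaction of -0.08 with a camera adjusted p of 0.0257, against an adjusted p of 0.503 with an estimated correlation, and fry, against no change, gave 0.508, while 0 members passed over all genes and 3 were lower over the list alone. The median was -0.05 with the batch as a block (camera, adjusted p = 0.0744), -0.10 in replicates 1 and 2 (0.227) and -0.05 in replicates 3 and 4 (0.235). The call was lost without replicate 1 (0.0678) or 4 (0.0545) of untreated Sat III siRNA cells, replicate 1 (0.118) or 4 (0.0851) of recovering Sat III siRNA cells, replicate 2 of untreated scrambled cells (0.0708) or replicate 4 of recovering scrambled cells (0.120).

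**Figure D3:**
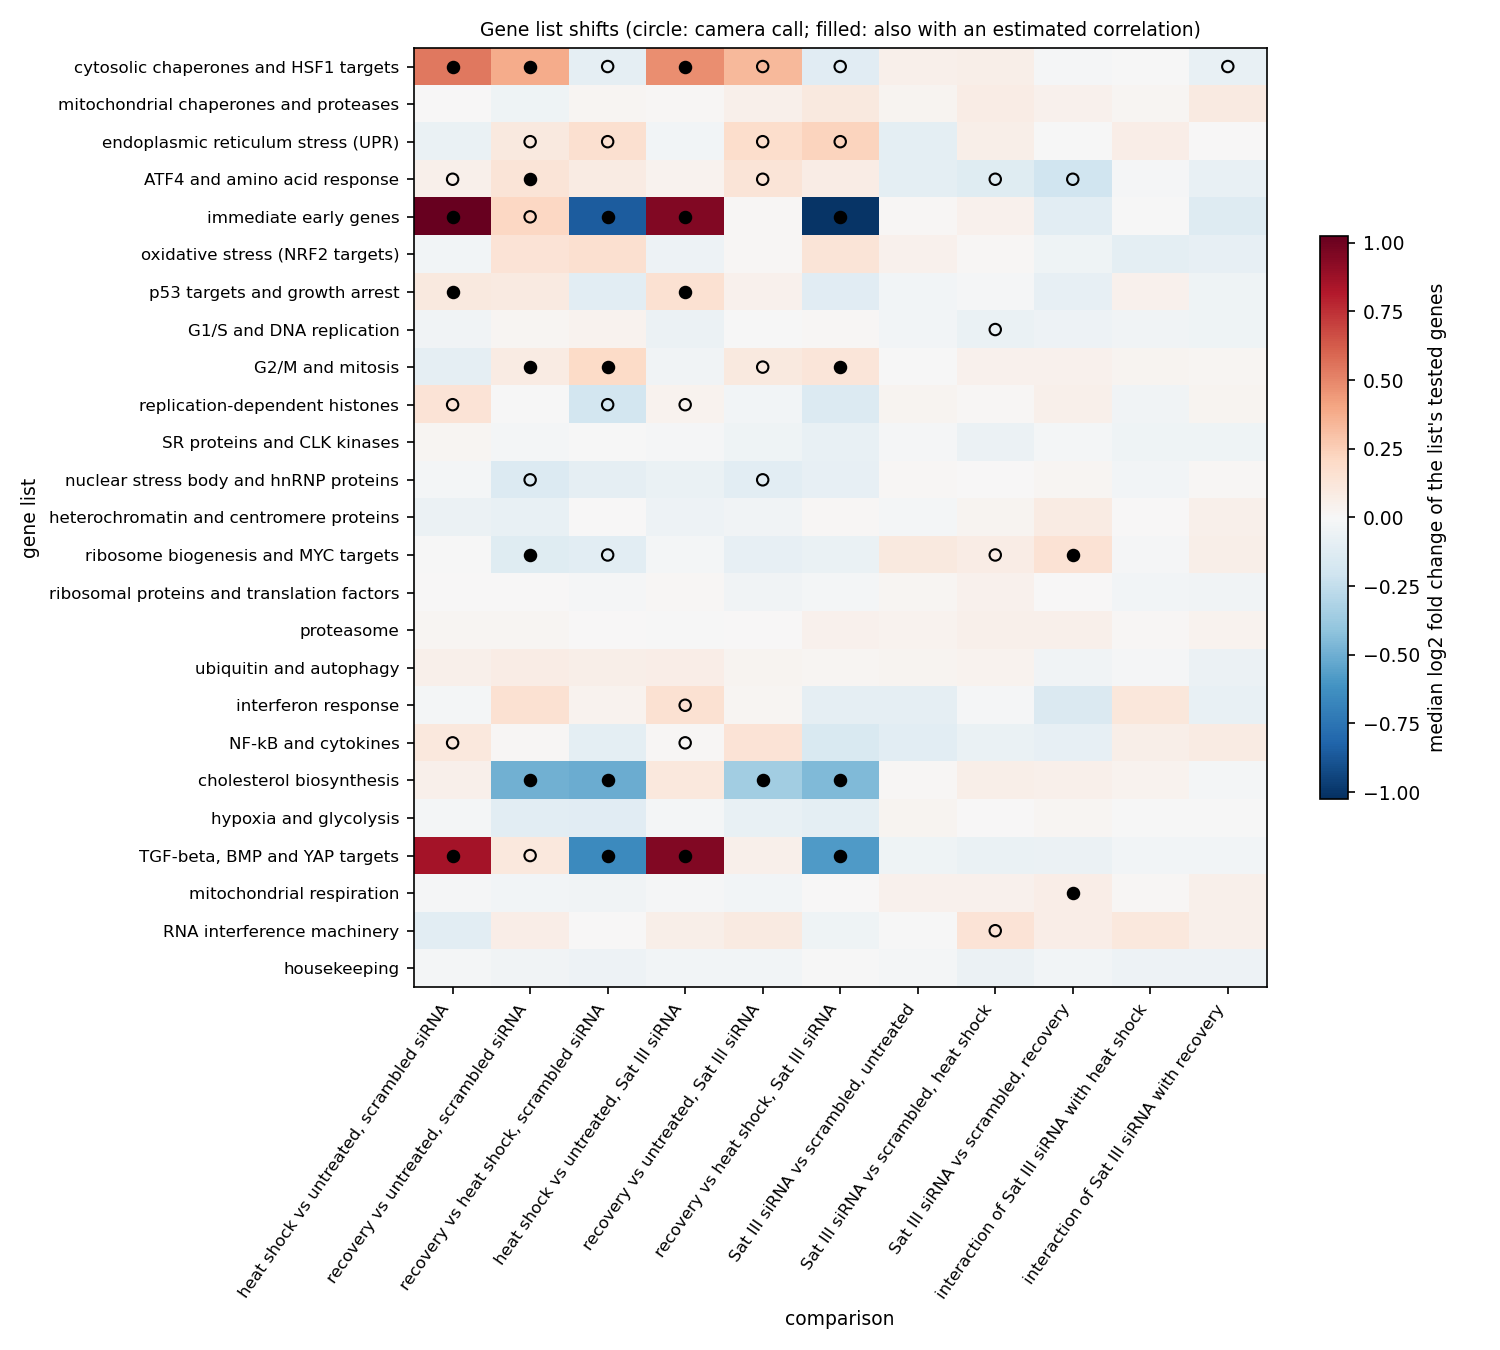
Median log2 fold change of the 25 tested gene lists (rows) in the 11 comparisons (columns), as a colour scale, with a circle where camera's adjusted p was under 0.05 and a filled circle where it also was with an estimated correlation. Of the 51 circles 24 are filled, and the untreated siRNA comparison and the interaction with heat shock hold none.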

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

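The tests on other splits of the arrays were chosen before the results were seen, and the tests of batch, of loss of heat-induced transcripts, of sequence-dependent repression, of swapped or dim arrays, of compressed folds and of milder heat were chosen only after the result was seen. In 52 pairs of a group of 4 arrays and a measure (3 array measures and 10 genes), a lowest or highest array was singled out when its gap to the nearest other array, relative to the group's range, exceeded the 95% limit of Dixon's test. That happened in 5 pairs, and chance alone singles out about 1 in 20. Scrambled heat shock replicate 4 had 13176 detected probes, against 13651 to 13724 on the others of its group, and an SD from its group mates of 0.203, against 0.176 to 0.177. Scrambled recovery replicate 4 had an SD of 0.220, against 0.192 to 0.193. The uncertain copy HSPA1B had 12.55 in Sat III siRNA recovery replicate 4, against 12.76 to 12.79, and ACTB had 14.0 in Sat III siRNA recovery replicate 3, against 13.71 to 13.76. The chaperone list differed between the arms in its recovery change, with a median interaction of -0.080, called by camera at the preset correlation, against an adjusted p of 0.503 with an estimated correlation and 0.0744 with the batch as a block. Among the 2227 tested probes without a single gene symbol, which the comparisons leave out, 118 were higher and 116 lower after heat shock in the scrambled arm, with a largest rise of 2.74 log2.

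Other splits of the same arrays into groups of the same sizes were fitted with limma. For each of the scrambled comparisons 1 of 35 splits, the real one, gave as many genes. The real count was 1184 against a highest of 1 among the others for heat shock, 1106 against 9 for recovery, and 2202 against 1 for recovery against heat shock. The share of 1 in 35 is under 0.05, but it is the smallest that 35 splits can give. Other splits also mix the treatments, which widens the spread and lowers their counts. Chance is therefore argued against for these comparisons and not excluded. The same holds at 1 of 35 for recovery in the Sat III siRNA arm (1217 against 234), recovery against heat shock there (2182 against 760) and the siRNA comparisons in untreated (618 against 95), heat-shocked (713 against 113) and recovering cells (1067 against 25). For heat shock in the Sat III siRNA arm the 10 splits were too few for a share under 0.05, with 773 genes in the real split and 0 as the highest of the others. For the interactions, 57 of 100 relabellings gave at least the 368 genes found at an unadjusted p under 0.05 for heat shock, and 61 of 100 at least the 387 found for recovery, so chance was not excluded. The highest of the others were 1422 and 2086, several times the real counts, which points to a structure among the samples whose nature was not tested.

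In all 3 treatments 335 genes passed in the siRNA comparison, with r of 0.648 to 0.725 between treatments over all genes. The batch as a block decides nothing about a batch effect: 100% of the 335 genes stayed past the threshold, but each batch holds arrays of both arms and the block moved their effects, at the median, by at most 2.01% of the median effect. Loss of heat-induced Sat III transcripts as the whole cause was argued against: among the 1067 genes called in recovery the median effect in untreated cells was 0.965 times that in heat-shocked cells (0.899 to 1.02 over pairs of Sat III siRNA arrays). Of the 137 genes changed at least 1.5-fold in untreated cells 113, or 82.5%, were lower. That share decides nothing about sequence-dependent repression of other transcripts by the siRNA, since it had been seen before the test was chosen and genes are not independent of each other. That explanation and an effect of Sat III transcripts present without heat stay open, because the siRNA sequence is not given in the sources used here.

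Scrambled untreated replicate 2 was examined because its SD from its group mates, 0.270, was the largest of the 22 arrays, against 0.172 to 0.207 in its group, though Dixon's test did not single it out. A heat-shocked or recovering sample in its place was argued against by its HSPA6 level of 4.89, against at most 4.87 on the other arrays of its group and at least 9.61 on heat-shocked or recovering ones. A Sat III siRNA sample was argued against by a score of -0.0070 over 491 siRNA genes, against -0.0085 to 0.0078 on the others and 0.442 to 0.448 in untreated Sat III siRNA cells. A dim array was argued against by its 14281 detected probes, against 13910 to 14132 on the others. The cause stays open, and no biological explanation was tested.

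HSPA6 rose less with heat shock in replicates 3 and 4, reaching 12.50 to 12.75 in the scrambled arm against 13.68 to 13.74 in replicates 1 and 2. A compression of fold changes alike for all genes on these arrays was argued against. Recovery changes of 195 genes picked in the Sat III siRNA arm had a ratio of 1.06 between the batches (0.968 to 1.16). Compression limited to bright signals or large changes was not tested. The heat shock changes of 296 genes picked there had a ratio of 0.854 (0.836 to 0.872). The untreated and heat-shocked groups of that arm hold mostly arrays of replicates 1 and 2. This favours genes that change more in those replicates and so works towards a lower ratio. The ratio goes with a milder heat exposure of replicates 3 and 4 but does not decide it. The temperature of each run is not given in the sources used here.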

How the results depend on the processing

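Of these alternatives, the fits with the 15 matching arrays of the authors' table, with the batch of replicates 1 and 2 against 3 and 4 as a block, and within each batch were chosen after seeing the data, as were the list tests with median scaling, with the batch and without single arrays. Counts are given in the order of the report, that is heat shock against untreated, recovery against untreated and recovery against heat shock in the scrambled arm, then the same in the Sat III siRNA arm, then the siRNA comparisons in untreated, heat-shocked and recovering cells, and the cause of a change was not tested unless stated. The main counts were 1184, 1106, 2202, 773, 1217, 2182, 618, 713 and 1067 with limma, and 0 for each interaction. Median scaling instead of quantile normalisation gave 251, 45, 457, 157, 43, 414, 44, 68 and 114. The authors' values with all columns as labelled, where 15 of the 22 columns match the scanner column of the same label, gave 0 in the 6 heat and recovery comparisons and in untreated siRNA cells, and 65 and 152 in heat-shocked and recovering ones. With the 15 matching arrays the counts that moved more than 1.5 times were 709 for recovery against untreated cells in the scrambled arm, 394 and 1293 for recovery against untreated and against heat shock in the Sat III siRNA arm, and 393, 473 and 652 for the siRNA comparisons. A minimum of 1.5-fold left 303, 143, 474, 296, 195, 566, 137, 175 and 189. Fitting only the groups compared gave 508 for recovery in the scrambled arm, 309 for untreated siRNA cells and 710 for recovering ones, and array weights gave 973 for untreated siRNA cells. Replicates 1 and 2 alone gave 567, 165, 1020, 470, 238, 1122, 193, 250 and 293, and replicates 3 and 4 alone 261, 76, 583, 68, 15, 342, 9, 37 and 151, with fewer arrays and with the lone untreated and heat-shocked Sat III siRNA arrays assumed to vary like the other groups. A variance trend with a robust prior gave 1 gene for the interaction with recovery. Under the remaining settings, among them no background correction, no detection filter or a stricter one, and the mean of probes or each probe, the counts stayed within 1.5 times. The interactions stayed at 0 otherwise, with 368 and 387 genes at an unadjusted p under 0.05 in the main analysis and 49 and 47 with median scaling.

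Leaving out replicate numbers or single arrays gave ranges of 662 to 1033, 431 to 969, 1223 to 2060, 325 to 738, 390 to 1007, 1234 to 1963, 226 to 583, 322 to 604 and 517 to 1013, and of 0 to 2 for the interaction with heat shock and 0 to 0 for that with recovery. Single arrays moved a count by more than 1.5 times in 3 comparisons. Without Sat III siRNA untreated replicate 1, 2 or 4 the recovery count of that arm was 635, 740 or 770 and the untreated siRNA count 374, 408 or 383, and without Sat III siRNA heat shock replicate 2 the siRNA count in heat-shocked cells was 434.

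The replicate number was also fitted as a block. The labels do not say whether the numbers pair the arrays. The median correlation of deviations was 0.166 for same-number pairs and -0.0374 for different numbers. It was 0.0865 for the other number on the same side of the division of replicates 1 and 2 against 3 and 4. Of 51 same-number pairs 32 correlated above 0.1, the lowest at -0.156, and 14 of the 22 arrays correlated best with their own number. This is a hint of a partial pairing, from the data and not from the design, and the main fit leaves it out. With this replicate block limma called 1394, 1448, 2553, 940, 1430, 2439, 784, 843 and 1328 genes and 0 for each interaction, and as a random effect 1355, 1418, 2553, 939, 1482, 2460, 802, 881 and 1326. The chaperone list's call in the interaction with recovery was lost with the replicate block (camera, adjusted p = 0.0877), and 0 other list calls were. The slide as a block was not run because no slide numbers are given in the sources used here.

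Of the 1470 results for named genes, 20848 comparisons with another setting kept direction and side of the threshold, 2205 fell below it, 415 rose past it and 17 reversed, and leaving out arrays gave 16926, 1395 and 108 without a reversal. Median scaling took 412 of these results below the threshold and reversed 0. With the mean of probes INSIG1 in the scrambled heat shock comparison reversed to -0.026. The other reversals came from the authors' values as labelled. For recovery against untreated scrambled cells they were CCND1 (0.086), JUND (0.080) and ULK1 (-0.018), and against heat-shocked ones H2AC18 (0.045). For recovery against untreated cells in the Sat III siRNA arm they were COX5B (-0.045), DHRS2 (-0.0062), DNAJB11 (-0.0070), IFIT1 (-0.11), KMT5B (-0.087), NOP14 (0.039), SLTM (0.0087) and XPO5 (0.042), and against heat-shocked cells COX5B (-0.018) and XPO5 (0.0015). For the siRNA comparisons they were KMT5B (0.0055) in untreated and HSPA5 (-0.058) in recovering cells.

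Of the 51 list calls 24 held with an estimated correlation and 27 did not. Median scaling ended 8, no background correction 0 and the 15 matching arrays 5, namely histones in heat-shocked Sat III siRNA cells (camera, adjusted p = 0.0918), ribosome biogenesis in the siRNA comparison of heat-shocked cells (0.10), ATF4 in recovering Sat III siRNA cells (0.0939), RNA interference (0.135) and the chaperone interaction (0.169). The authors' values as labelled ended 21. These settings added 12, 5, 7 and 13 calls in turn. Fry, against no change, ended 1 and added 48. For genes not above background in a group, the detected signal sets only a lower limit of the fold.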

Other observations

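Several gene groups with too few tested members for a list test also held genes that passed. SNHG4, a host gene of small nucleolar RNAs, fell with heat shock by 0.70 in the scrambled and 0.76 in the Sat III siRNA arm (limma, adjusted p = 1.1e-04 and 2.9e-04), was higher in recovery than in heat shock by 0.88 and 1.02, and was higher by 0.45 with Sat III siRNA in recovering cells, a call lost with median scaling (limma, adjusted p = 0.543). The metallothionein gene MT1X was lower by 0.49 in recovering than in untreated cells in both arms (limma, adjusted p = 0.00476 and 0.00761), where the Sat III siRNA call was lost without untreated replicate 4 (0.0608) and both with median scaling (0.106 and 0.146). With heat shock in the scrambled arm, SNORD46 rose by 2.18 ± 0.23 and the ribosomal protein gene RPL37 by 0.80 ± 0.09, while SNORA25 fell by 0.97 ± 0.16 and SNORD14A by 0.93 ± 0.10. In the oxidative stress list, whose smallest adjusted p by camera was 0.0605 (interaction with recovery), NQO1 rose by 0.41 ± 0.09 and HMOX1 fell by 0.55 ± 0.10 in recovering scrambled-siRNA cells. TRA2A, a splicing regulator gene, was lower with Sat III siRNA by 0.56, 0.64 and 0.75 in untreated, heat-shocked and recovering cells, and IFITM2, an interferon-induced gene, by 0.81 and 0.85 in heat-shocked and recovering ones.

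Of the 25 tested lists 9 did not pass in any of the 11 comparisons with camera in the main analysis. Besides the oxidative stress list, their smallest adjusted p was 0.0618 for ubiquitin and autophagy (recovery, scrambled arm), 0.168 for the proteasome, 0.215 for heterochromatin and centromere proteins, 0.321 for mitochondrial chaperones and proteases and for ribosomal proteins and translation factors, 0.342 for SR proteins and CLK kinases, 0.376 for housekeeping genes and 0.439 for hypoxia and glycolysis. Single members passed with limma all the same, among them ULK1, a kinase gene that starts autophagy, at 0.41, ENO2, a glycolytic enzyme gene, at 0.76 and CBX1, a heterochromatin protein gene, at -0.46 in recovering against untreated scrambled-siRNA cells. With median scaling these calls, those of NQO1 and HMOX1, and those of TRA2A in untreated and heat-shocked cells were lost.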
